A study of Mus musculus with 26 samples.

How the data were processed

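The series comprised 26 samples of C2C12, a mouse myoblast line that fuses into multinucleate myotubes when serum is lowered. Per the labels' protocols, cells grew in 20% serum and differentiated in 2% horse serum. Peak lists of 16 samples in 8 groups of 2 libraries were used. They covered ChIRP-seq, in which biotinylated probes pull down an RNA with the chromatin it touches, here the DRR enhancer RNA in myotubes with 2 separate probe pools. They also covered ChIP-seq of SMC3, a core subunit of the cohesin ring, in myoblasts, myotubes and myotubes transfected with siDRR. ATAC-seq, which marks accessible chromatin by transposase insertion, was done in myotubes transfected with control, siDRR or siSmc3. The other 10 samples, the inputs and the LacZ probe controls, were not analysed here, so no background library stands beside the ChIRP or ChIP values.

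Each list held 5 columns without a header, in coordinates of mouse build mm9 per the submitters' processing notes. Those notes name CASAVA 1.8.2, bcl2fastq 2.17.1, cutadapt 1.12, Bowtie 1.1.1, Bowtie2 2.2.4, MACS 1.4.2 and MACS2, without saying which served which assay. The control used in peak calling, read filters, the shift applied to ATAC reads and the calling threshold are not given in the sources used here. The last column is the deposited score of each peak, made by the authors' peak caller, and its scale is not stated. Scores started at 50 in the SMC3 lists and at 30 in the ATAC lists. There was 1 list per library, so peaks were not called on pooled replicates. ChIRP lists held single-base summits, ATAC and SMC3 lists held intervals. No list gave read counts: the sequencing depth is unknown, and scores were used only to rank or filter peaks inside a list. A longer list can come from deeper sequencing as well as from more binding. The labels name no separate cultures for the replicates, so the spread between them may be technical.

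Start positions were converted to 1-based coordinates. Peaks on the mitochondrial chromosome and unplaced contigs were left out. ChIRP summits were widened by 250 bp on each side, a width chosen after the lists had been seen. For each comparison the peaks of the 4 libraries were merged into regions where they overlapped by at least 1 bp, and a library called a region if any of its peaks touched it. A region was counted as lost when both libraries of the first group and neither of the second called it, and as gained in the opposite case. These words describe peak calls, not a test of occupancy. Totals differ slightly between comparisons because merging depends on the libraries joined. A rank percentile is the place of a peak by score in its own list, with 100 the best, and a region takes that of its best peak. No pair of lists was a repeat deposit: at most 1.4% of the shorter list's intervals recurred exactly in another list.

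Regions called in exactly 2 of 4 libraries fall into 6 patterns. Their expected numbers were fitted from library effects alone, a Rasch model in which longer lists take more regions. The observed over expected ratio was computed for the group split, for libraries that share a replicate number and for crossed numbers. Because the model fits each library's total, the ratio measures whether group mates agree, and says nothing of direction. Intervals of 95% came from 1000 resamples of 10 Mb genome blocks; they compare these libraries, not the conditions. With 2 libraries against 2, an exact permutation test cannot go below p = 0.333, so that test cannot pass at 2 libraries a group; no parametric test over libraries was run.

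Overlap with ChIRP regions was set against 1000 circular shifts within chromosomes (two-sided, smallest p 0.002). Loss at ChIRP or SMC3 regions was given as a Mantel-Haenszel odds ratio within 10 strata of mean rank percentile, with block intervals. For loss at ChIRP regions, the design called for regions found in at least 1 replicate of each probe pool if fewer than 200 were found in all 4 ChIRP libraries. That case applied. Overlap of the knockdowns, which share their controls, was set against 200 sets simulated from library effects over 6 libraries.

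The procedures were tested on simulated data shaped by the list lengths of the comparison of SMC3 in myotubes with siDRR, over 30797 regions. In the test of the ratio, regions were drawn independently, with no effect of the replicate number. False calls from that effect were therefore not tested. With no planted effect, the interval of the ratio excluded 1 in 0 of 20 draws. With 300 regions planted as lost and 300 as gained it did so in 20 of 20. With 300 planted as lost alone it did so in 7 of 20, at a mean ratio of 1.017, and with 1000 planted as lost alone in 20 of 20, at 1.023. A one-way loss thus moves the ratio little, being largely absorbed by the library effects, but a loss of 1000 regions was called at the simulated spread. The interval observed under siDRR, 0.989 to 1.032, holds both 1 and 1.023, so it decides neither way. As the simulation had no effect of the replicate number, 1.023 is only a rough guide for the real lists. An odds ratio planted at 2 was estimated at 2.06 on average over 13876 regions. The planted trait was far more common than in the 32 SMC3 regions that met a ChIRP region, so numbers that small were not covered. One-way losses were also planted in the real siDRR lists, a check added after the data had been seen. Removing 321 regions ranked like the lost ones left 53.6% of lost and gained regions lost at equal length, and removing 895 regions of any rank 66.6%, so equal lengths hide a one-way loss of weak regions. Unrelated random regions passed the shift test in 1 of 20 draws. They were placed evenly along chromosomes, so this does not cover real lists that both favour the same parts of a chromosome.

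Which regions the text names was fixed before the data were examined: in each comparison the 10 lost and 10 gained regions with the highest mean rank percentile in the libraries that called them, and the 10 highest ChIRP regions of all 4 libraries. The text gives some of each in full. The rule also named genes and the Myod1 and Myog loci, and 8 gene lists had been fixed for a test near transcription starts. No mm9 annotation was used here and coordinates were not converted, so neither was run, and regions are given by position with no gene assigned. During exploration, windows recalled from memory for the Myod1 and Myog loci were viewed, with positions unverified. The region on chromosome 1 at 136185772 to 136191545 lay in a window viewed in this way. The rank rule also names it. The alternatives fixed at the same time were the better-scoring 50% of each list, lists cut to equal length, 50% coverage of a region, merging within 500 bp, leaving out each replicate, a replicate block and unstratified odds ratios. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.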

Results

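Genome-wide maps were collected of where the DRR enhancer RNA, the cohesin subunit SMC3 and accessible chromatin lay in C2C12 cells. Each of the 8 groups had n = 2 libraries. SMC3 lists held 30955 and 33154 peaks in myoblasts, 15056 and 26765 in myotubes, and 8384 and 23196 in myotubes with siDRR. ATAC lists held 58138 and 99548 peaks in control myotubes, 69841 and 98592 with siDRR, and 80897 and 103056 with siSmc3. ChIRP lists of probe pool 1 held 3776 and 68812 summits, those of pool 2 held 23087 and 20295. The level of DRR or Smc3 RNA after knockdown was not analysed here.

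**Figure D1:**
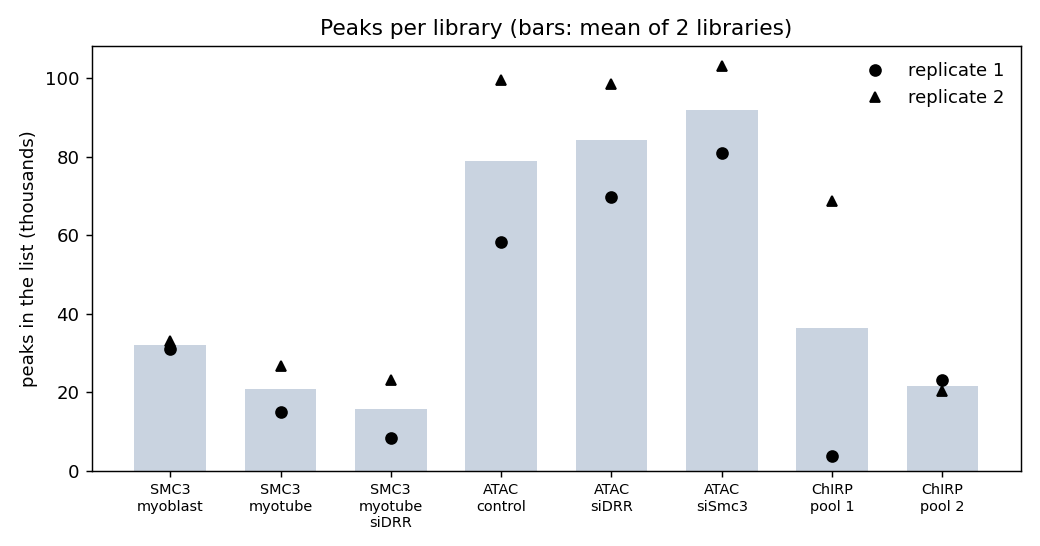
Number of peaks in each list (vertical axis, in units of 1000) for the 8 groups (horizontal axis); bars are the mean of 2 libraries, circles replicate 1 and triangles replicate 2. In the SMC3 myotube groups the replicates differ more than the groups do, and the lists of ChIRP pool 1 range from 3776 to 68812 summits.

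The first comparison asked how cohesin sites changed as myoblasts became myotubes. Most SMC3 regions of myotubes were already present in myoblasts: of 13837 regions called in both myotube libraries, 13017 were called in both myoblast libraries as well. Another 5458 regions were called in both myoblast libraries and in neither myotube library, against 336 that appeared only in both myotube libraries. Lost and gained regions were both weak, with median rank percentiles of 29.6 and 28.5 in the lists that held them, against 76.7 for the regions of all 4 libraries. Of the gained regions, 46.1% overlapped an accessible region of control myotubes, against 28.1% of the lost and 24.9% of those in all 4; the differences between these shares were not tested.

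The highest-ranked lost region lay on chromosome 8 (130496380 to 130498417, mm9), at rank percentiles of 88.9 and 94.9 in the 2 myoblast lists. The next were on chromosome 3 (131583713 to 131584699) and chromosome 5 (104082887 to 104084054), with mean percentiles of 86.2 and 84.7. A broad region of 10255 bp on chromosome 8 (87496946 to 87507200) was also among the 10. The highest-ranked gained region was on chromosome 6 (31024807 to 31027869, 3063 bp), at 89.2 and 89.1 in the 2 myotube lists. The second was on chromosome 1 (136185772 to 136191545, 5774 bp), at 94.5 and 64.9. Chromosome 18 (47152561 to 47153976) and chromosome 5 (144677905 to 144679076) followed, at means of 76.4 and 76.2.

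Myoblast lists held 32054.5 ± 1555 peaks and myotube lists 20910.5 ± 8280 (SD, n = 2 each), p = 0.333 in a two-sided exact permutation test, the smallest the design allows. Libraries of a group agreed more than library effects alone gave, with an observed over expected ratio of 1.104 (95% interval 1.092 to 1.118). With full lists 94.2% of the lost and gained regions were lost, and with lists cut to 15056 peaks each 56.5%, at 1023 lost and 788 gained and a ratio of 1.57 (1.52 to 1.63). Equal lengths draw lost and gained toward balance, so this does not separate shorter lists from a loss of sites.

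Knockdown of the DRR RNA addressed whether cohesin in myotubes depended on it. Of 13876 SMC3 regions called in both myotube libraries, 7142 were called in both siDRR libraries and 895 in neither. Only 40 regions appeared in both siDRR libraries and neither myotube library. The 895 lost regions were weak, at a median rank percentile of 25.3 against 75.6 for the 7142, and 63.5% of them overlapped a myoblast SMC3 region, against 99.1% of the 7142. Because the sets differ in rank, these shares alone do not show a trait of the lost regions.

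The highest-ranked lost region was on chromosome 9 (53676757 to 53677991), at rank percentiles of 95.9 and 63.8 in the myotube lists. The second was the chromosome 1 region (136185772 to 136191545) that also ranked second among regions gained on differentiation. Others lay on chromosome 4 (63140648 to 63141963), chromosome 2 (180166672 to 180167681) and chromosome 1 (187577900 to 187579235), at mean percentiles of 75.3, 71.5 and 69.7. Among the gained, chromosome 8 (88049160 to 88051639) ranked first at 64.8, and the tenth, on chromosome 13 (60397219 to 60398533), stood at 30.6.

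The siDRR lists held 15790 ± 10474 peaks (SD, n = 2), against 20910.5 ± 8280 in myotubes (p = 0.667, two-sided exact permutation test). The observed over expected ratio was 1.01 (0.989 to 1.03). That interval holds 1 and also 1.023, the value with 1000 regions planted as lost. The planted value had no effect of the replicate number, so it is only a rough guide here. With the replicate number as a block and full lists the ratio was 1.02 (0.998 to 1.039), which also holds 1. The full lists therefore do not decide whether group mates agreed more than list lengths alone gave. With lists cut to 8384 peaks each, 346 regions were lost and 289 gained (54.5% lost, against 95.7% with full lists), and the ratio was 0.784 (0.731 to 0.841), below 1, but 1.07 (1.02 to 1.13), above 1, with the replicate number as a block. The labels give no transfection for the myotube libraries that siDRR was set against.

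**Figure D2:**
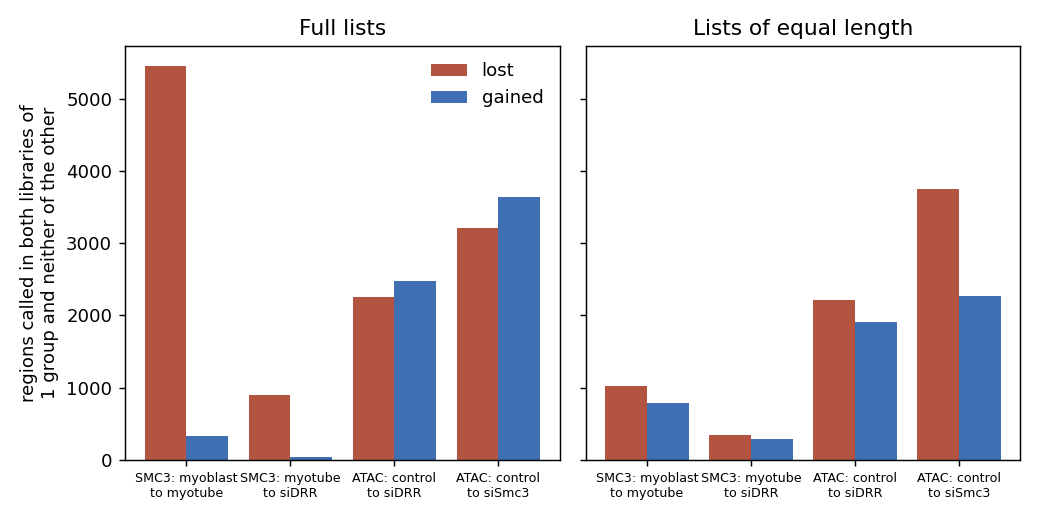
Regions called in both libraries of 1 group and neither of the other (vertical axis), for 4 comparisons, with lost regions in red and gained in blue. The left panel has full lists and the right panel lists of equal length; the SMC3 counts go from 895 lost and 40 gained under siDRR to 346 and 289.

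At the chromosome 1 region the libraries could be read side by side. SMC3 peaks lay at 136185772 to 136191545 in the first myotube library (score 285.77) and at 136186070 to 136188200 (score 236.49) and 136189245 to 136191349 in the second. Neither myoblast library and neither siDRR library had a peak within 10 kb of the region. Control ATAC peaks at 136185963 to 136186695 and 136186089 to 136186576 fell inside it in both libraries, at rank percentiles of 49.4 and 25.2. Control replicate 1 also had a peak inside it at 136186915 to 136187953, at a percentile of 31.2. Under siDRR, ATAC peaks inside it were called in replicate 2 alone. They lay at 136186210 to 136186802, at a percentile of 65.6, higher than in either control list, and at 136186804 to 136187222. Under siSmc3 neither library called an ATAC peak inside the region. ChIRP summits lay at 136186925 in replicate 2 of pool 1, at rank percentile 70.5. In pool 2 they lay at 136187300 and 136187974 in replicate 1, both at 28.6, and at 136187090 in replicate 2, at 98.8. Replicate 1 of pool 1 had none. With lists of equal length the region was called in the first myotube library only, so it no longer counted as lost under siDRR; it still counted as gained on differentiation. The ATAC region that both control libraries had called inside it was then called in control replicate 1 only. With the better-scoring 50% neither control library called that ATAC region, so the ATAC loss under siSmc3 ended as well.

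**Figure D3:**
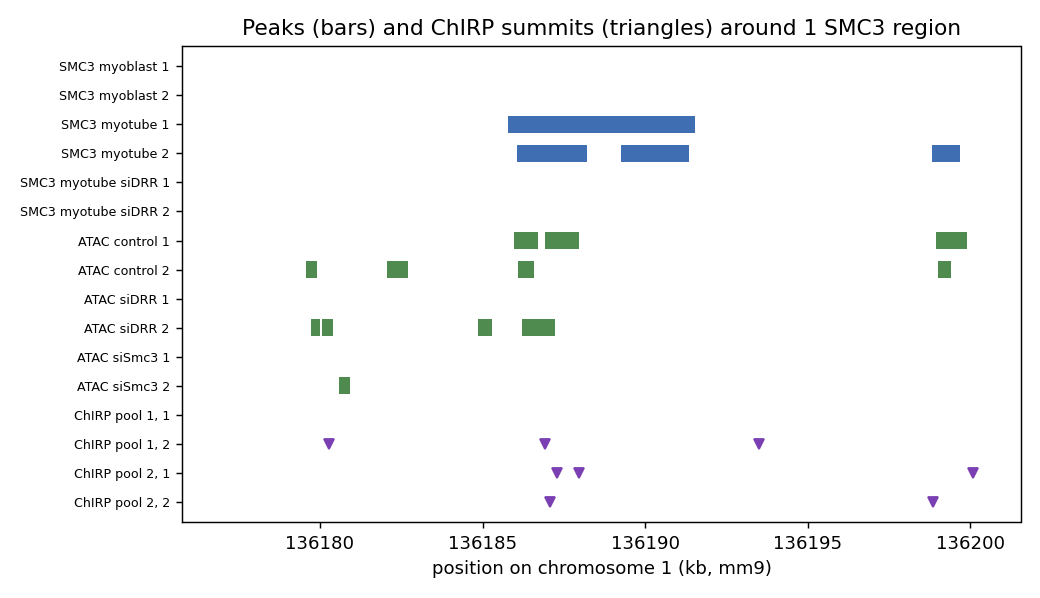
Peaks (bars) and ChIRP summits (triangles) of all 16 libraries along chromosome 1 (horizontal axis, kb, mm9), 10 kb either side of the SMC3 region at 136185772 to 136191545; each row is 1 library. SMC3 bars appear in the 2 myotube rows and in no myoblast or siDRR row.

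ATAC-seq asked whether either knockdown changed accessibility. Under siDRR, 2257 regions called in both control libraries were called in neither siDRR library, and 2480 were gained, while 27933 were called in all 4 libraries. Median widths were 679 and 603 bp for lost and gained regions and 1322 bp for regions of all 4. These are widths of merged regions, and merging the peaks of more libraries widens a region by construction. Single peaks in the control and siDRR lists had median widths of 517 to 704 bp, so lost and gained regions are not shown to be narrow. SMC3 regions of myotubes overlapped 3.41% of the lost, 15.0% of the gained and 10.1% of the shared regions.

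Under siDRR the strongest loss by rank was on chromosome 12 (9098401 to 9099411), at percentiles of 90.0 and 91.2 in the control lists. Loss followed on chromosome X (147389899 to 147390667) and chromosome 3 (137188623 to 137189710), at means of 84.0 and 82.9. The highest-ranked gains were on chromosome 17 (13132844 to 13134053), chromosome 13 (11658605 to 11659367) and chromosome 14 (45452597 to 45453519), at 78.2, 77.9 and 77.3.

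Control lists held 78843 ± 29281 peaks and siDRR lists 84216.5 ± 20330 (SD, n = 2 each; p = 1 in a two-sided exact permutation test). Group mates agreed more than list lengths gave, at a ratio of 1.089 (1.061 to 1.118). Libraries of the same replicate number also did, at 1.05, and crossed libraries did not, at 0.719. By the log2 product of counts, in which list lengths cancel, same-numbered libraries shared more than group mates with full lists (-1.12, -1.29 to -0.95), and at equal length (-0.70, -0.91 to -0.48), but not with the better-scoring 50% (0.05, -0.37 to 0.52).

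Under siSmc3, 3210 ATAC regions were lost and 3636 gained, and 25618 were called in all 4 libraries. Both sets were larger than under siDRR, but the difference between the knockdowns was not tested. SMC3 regions of myotubes overlapped 5.61% of the lost and 8.69% of the gained regions, against 9.70% of those in all 4.

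The highest-ranked losses were on chromosome 1 (20623191 to 20624186), chromosome 13 (102765879 to 102766751) and chromosome 11 (110735600 to 110736498), at mean percentiles of 91.4, 90.8 and 90.5. All 10 named losses stood at 86.4 or higher. The highest gain was on chromosome 4 (117330880 to 117332007), at 91.1. A gain overlapping it ranked eighth under siDRR (117330876 to 117331771), at 75.2. Chromosome 11 (72548100 to 72549143) and chromosome 16 (76782741 to 76783559) followed, at 89.8 and 88.9.

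The siSmc3 lists held 91976.5 ± 15669 peaks (SD, n = 2), p = 0.667 against control in a two-sided exact permutation test. The ratio for the group split was 1.21 (1.18 to 1.23), against 1.07 for the same replicate number and 0.569 for crossed numbers, and the log2 product of group mates over same-numbered libraries was -0.82 (-0.95 to -0.69). That product was -0.14 (-0.33 to 0.02) at equal length and turned to 1.02 (0.73 to 1.33) with the better-scoring 50%. With lists cut to 58137 peaks, 3749 regions were lost and 2272 gained, so that 62.3% of them were lost against 46.9% with full lists.

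**Figure D4:**
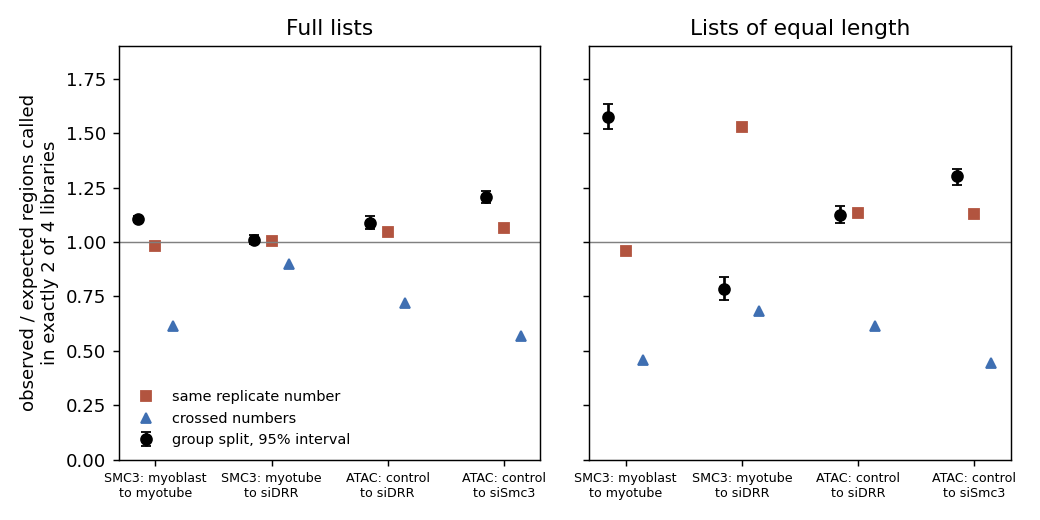
Observed over expected number of regions called in exactly 2 of 4 libraries (vertical axis) for 4 comparisons, with full lists (left) and lists of equal length (right). Black circles are the group split with 95% block intervals, red squares libraries of the same replicate number and blue triangles crossed numbers; at equal length the group split of SMC3 under siDRR is 0.784, and 1.07 (not drawn) with the replicate number as a block.

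Many of the ATAC regions lost under siDRR were also lost under siSmc3. Over the 6 libraries, 1202 regions were lost under both, which was 53.3% of the siDRR losses and 38.0% of the siSmc3 losses. Both knockdowns were set against the same 2 control libraries, so overlap arises without any shared effect. Library effects alone gave 1086 shared losses (95% of simulated sets 1023 to 1142), and independent lists 185.2, but the simulated sets held 2458 siSmc3 losses against 3163 observed, so the counts are not on the same footing. Shared gains numbered 297, against 214.9 (187 to 245) simulated and 75.9 for independent lists. The simulation had no term for the replicate number, and the controls could not be split with 2 libraries on each side. The higher observed counts are therefore not shown to be a shared effect of the knockdowns.

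ChIRP asked where the DRR RNA touched the genome, with 2 probe pools as a guard against sites that a probe binds by itself. Replicates of a pool shared more of the smaller list than the pools did. In pool 1, 97.4% of the 3700 regions of replicate 1 recurred among the 67929 of replicate 2, which was 5.30% of the regions of either. In pool 2, 62.2% of the smaller list recurred in the other, 41.1% of the regions of either. Between pools the shared part of the smaller list was 3.27% to 4.16%. Of 97348 ChIRP regions, 101 were called in all 4 libraries and 1146 in at least 1 replicate of each pool. The 68032 regions of pool 1 overlapped those of pool 2 in 1152 cases, against 803 after circular shifts (p = 0.002, two-sided permutation test, the smallest possible).

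The highest-ranked region of all 4 libraries was on chromosome 17 (4626087 to 4626607), at a percentile of 99.8 or higher in each. Chromosome 8 (12377980 to 12378698), chromosome 11 (24999912 to 25000426) and chromosome 13 (113303340 to 113303907) followed, at means of 99.4, 99.0 and 98.4. The tenth, on chromosome X (119944777 to 119945285), stood at 96.2.

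Whether the RNA met cohesin was asked by overlap with the SMC3 regions of both myotube libraries. Of the 101 regions, 1 overlapped SMC3 (0.990%, exact 95% interval 0.0251% to 5.39%), against 1.06% after shifts (p = 1, two-sided permutation test). Without replicate 1 of each ChIRP and SMC3 group, 29 of 753 regions overlapped it (3.85% against 2.09%, p = 0.006 in the permutation test), and without replicate 2, 2% of 150 did (p = 0.456, permutation test). The set found in both pools, for which this overlap was chosen after the data had been seen, overlapped more often: 32 of 1146 (2.79%) against 1.16%, p = 0.002 in the same permutation test. It also met accessible regions of control myotubes more often, 7.33% against 2.85%, with p = 0.002 in the permutation test. Among accessible regions, those with SMC3 carried a ChIRP region of both pools in 0.192% of cases and those without in 0.211%, an odds ratio of 0.912 (0.313 to 1.73).

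**Figure D5:**
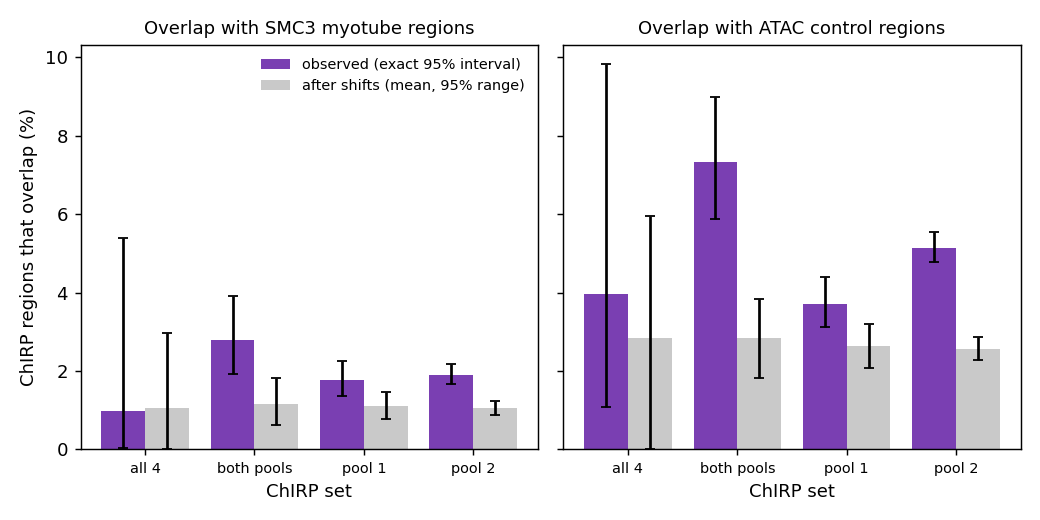
Share of ChIRP regions that overlap SMC3 regions of myotubes (left) or accessible regions of control myotubes (right), in percent (vertical axis), for 4 ChIRP sets: all 4 libraries, at least 1 replicate of both pools, both replicates of pool 1, and both replicates of pool 2. Purple bars are observed with exact 95% intervals, grey bars the mean and 95% range of 1000 shifts; the set of both pools overlaps SMC3 in 2.79% against 1.16%.

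SMC3 regions that met a ChIRP region of both pools were few. Of 32 such regions, 5 were lost under siDRR (15.6%), against 6.43% of 13844 others. The odds ratio within rank strata was 2.77 with an interval of 0.627 to 9.38, so no difference was detectable with this number of regions. The estimate fell below 1 without replicate 2, at 0.176 (0 to 1.02), where 1 of 3 regions was lost. It was also below 1 with pool 1 alone, at 0.616 (0 to 1.82), where 3 of 69 were lost. Both intervals include 1, so neither shows a change of direction. With summits widened by 500 bp the odds ratio was 1.08 (0.271 to 2.71).

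Accessible regions at SMC3 sites were lost less often than other accessible regions in both knockdowns. Under siDRR, 77 of 3636 ATAC regions with SMC3 were lost (2.12%), against 2180 of 34928 without (6.24%), an odds ratio of 0.199 (0.158 to 0.253). Under siSmc3 the shares were 4.93% of 3649 and 8.66% of 34981, an odds ratio of 0.384 (0.322 to 0.455). Control regions that were missing from the other control library were also rarer at SMC3 sites, with odds ratios of 0.233 (0.208 to 0.262) for replicate 1 and 0.630 (0.590 to 0.671) for replicate 2, a comparison added after the data had been seen. Without replicate 2 the odds ratios of loss were nearer 1, at 0.442 (0.406 to 0.482) under siDRR and 0.609 (0.564 to 0.658) under siSmc3.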

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

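The tests of list length, with its planted losses, of group against crossed libraries and of control drop-out for siSmc3 were chosen after their result was seen, and the strata of rank and width were added after the lists had been seen.

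ChIRP summits on unplaced contigs stood outside the comparisons above: 11 and 579 in the replicates of pool 1, and 103 and 87 in those of pool 2. They were picked out because no comparison used them, not as a sign of binding. Chromosome Y together with its unplaced contigs held 390 summits in replicate 2 of pool 1, against 5, 12 and 13 in the other ChIRP lists. The LacZ and input libraries that would show the background were not analysed here.

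SMC3 loss under siDRR was nearly all in 1 direction. At equal length 54.5% of the lost and gained regions were lost, but planted one-way losses of regions ranked like the lost ones gave 53.6%, so shorter lists and a true loss cannot be told apart. Whether the knockdown changed which regions were called also stays open: at equal length, group mates shared more than crossed libraries by 0.40 on the log2 scale of products (0.10 to 0.74), and with the better-scoring 50% (0.821, 0.226 to 1.396) and 50% coverage (0.69, 0.08 to 1.20), but the interval reached below 0 with full lists (-0.06 to 1.04) and with merging within 500 bp (-0.05 to 1.06). The values do not decide it, and the rule that the intervals of full and equal lists must both exceed 0 was set after these values were seen. Group mates also shared less than libraries of the same replicate number, by a log2 product of -1.95 (-2.26 to -1.64) at equal length, so the replicates may differ by a batch the labels do not name.

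The probe pools shared few ChIRP regions. If weak summits diluted the overlap, strong ones should recur; the highest share of a library's 500 strongest summits found in the other pool was 25.6%, and the lowest 2.2%, which leaves this open for pool 2. Within a pool at least 91.8% of the 500 strongest recurred in the other replicate. That is consistent with each pool pulling down its own set of sites, and a pool's own sites could be probe binding or parts of the RNA that each pool reaches. LacZ probe libraries, which bear on the first, were not analysed here.

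Lower ATAC loss at SMC3 sites was not explained by the rank or width of the regions there. Within quintiles of rank and width the odds ratios stayed at 0.207 under siDRR and 0.380 under siSmc3. Without strata they were nearer 1, at 0.325 and 0.547. The strata thus moved them away from 1, the opposite of what stronger regions at SMC3 sites would give. More reproducible calling at SMC3 sites remains: between the control libraries alone, missing regions were rarer there, with an odds ratio of at most 0.630. A candidate explanation for both knockdowns is therefore peak calling, and a knockdown effect that spares SMC3 sites cannot be separated from it with these lists.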

How the results depend on the processing

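Alternatives with other summit widths, single pools for the overlap and odds ratios, width strata and equal lists with the replicate block were chosen after seeing the data. So was the overlap of SMC3 with ChIRP regions of at least 1 replicate of each pool. With 50% coverage (19 results) and merging within 500 bp (12 results) each result kept its side of the threshold or stayed within 1.5 times. Keeping the better-scoring 50% of each list gave, for SMC3 lost and gained, 2431 and 161 in myotubes and 550 lost under siDRR; for ATAC, 1067 and 1286 under siDRR, 1966 and 2013 under siSmc3 and 560 shared losses; and 40 regions in all 4 ChIRP libraries. Lists of equal length gave 1023 and 788, 346 and 289, 2272 ATAC gains under siSmc3 and 28 ChIRP regions, and reversed the SMC3 ratio under siDRR to 0.784. Fewer peaks change the counts by construction. With the replicate number as a block the reversal was absent, at 1.07 (1.02 to 1.13). ChIRP counts were 1146 for at least 1 replicate of each pool, 3603 for pool 1 and 12511 for pool 2. Their overlap with SMC3 went above the shifted value, against just below it in the main set, at 2.79%, 1.78% and 1.91%; the cause was not tested.

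Leaving out a replicate left 1 library per group, so counts of regions carry no test, while ChIRP overlaps keep their shifts and odds ratios their block intervals. Lost and gained regions then ranged from 11214 to 17074 and 1206 to 4569 for SMC3 in myotubes, and 6864 to 7777 and 1076 to 3159 under siDRR. ATAC ranged from 28261 to 34429 and 34160 to 39005 under siDRR, and 30131 to 34288 and 38666 to 51686 under siSmc3. Shared losses were 23440 to 25248 and shared gains 5695 to 8306. ChIRP regions of all remaining libraries were 150 to 753, and their SMC3 overlap 2% to 3.85%. ATAC loss under siDRR at lost SMC3 regions had odds ratios of 0 with the better-scoring 50% and 0.700 at equal length. Under siSmc3 these were 1.72 and 1.29. ATAC gain at SMC3 sites under siDRR gave 1.398, 1.49 at equal length and 0.893 in width strata, and under siSmc3 0.972 with the better-scoring 50%; the cause was not tested. The odds ratio of SMC3 loss at ChIRP regions ranged from 0.176 to 1.82, and was 0.616 with pool 1. ATAC loss at SMC3 sites ranged from 0.223 to 0.442 under siDRR and 0.346 to 0.609 under siSmc3. ATAC peak numbers under siDRR over control were 0.990 to 1.20. The ratio for splits needs 4 libraries and was not run so, and the odds ratio of SMC3 loss at ChIRP regions had no value at equal length, when no region met a ChIRP region.

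The replicate numbers are shared by number only. Deviations of same-numbered libraries correlated at 0.0422 to 0.188 in SMC3 and 0.138 to 0.161 in ATAC. With 2 libraries per group, pairs of unlike number gave the same values with a minus sign. Replicate 2 held the longer list in every SMC3 and ATAC group, so these values do not separate list length from a shared batch. With the replicate block the ratios were 1.103, 1.02, 1.20 and 1.36 in the order of the report with full lists, where no call changed; at equal length it turned the SMC3 ratio under siDRR as given above. The gene list test was not run at any window around transcription starts. Depth is unknown, so list length and depth cannot be separated.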

Other observations

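The simulation of SMC3 gain and loss and the stepwise count were chosen after their result was seen, and the tests of SMC3 loss at gained regions, ATAC loss at lost SMC3 regions and ATAC gain were added after the main comparisons had been seen.

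SMC3 regions that appeared on differentiation were often the ones missing after siDRR. Over the 6 SMC3 libraries, 161 of 336 gained regions (47.9%) were called in neither siDRR library, against 563 of 13016 (4.33%) that both myoblast libraries also called. The odds ratio within rank strata was 5.43 (4.21 to 7.01), and 6.85 (4.91 to 9.60) with lists of equal length. With the better-scoring 50% it was 9.21 (6.31 to 14.02), at a share of 55.3% against 46.55% simulated (31.86% to 61.36%). The value at equal length does not exclude weaker peaks in shorter lists, because at equal length library effects alone gave an unstratified odds ratio of 17.79 (13.81 to 22.87), above the observed 14.75. Both sets rest on the same myotube libraries, and with full lists library effects alone gave a share of 47.8% (35.0% to 58.5%). This simulation, too, had no term for the replicate number. The simulated sets held fewer regions, 84.73 gained (69 to 102) and 40.45 gained and then lost (29.98 to 53), so library effects alone do not give the observed counts and the shares are not on the same footing. Whether siDRR removed SMC3 preferentially from regions gained on differentiation stays open, a reading adopted only after the simulation was seen. At equal length the observed share, 23.2%, lay below the simulated 31.3% (27% to 34.8%), with 616 gained against 395 simulated and 143 gained and lost against 123.6 (105 to 141).

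Of 13836 SMC3 regions in both myotube libraries, 336 were in neither myoblast library and 161 of those in neither siDRR library. Of these 161, 66 met a control ATAC region, and 1 of the 66 also met a ChIRP region of both pools, the chromosome 1 region at 136185772 to 136191545. The steps were put together after that region had been seen, so the count of 1 is a description and not a test.

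ATAC loss was set against SMC3 loss. Under siDRR, 6 of 208 ATAC regions at SMC3 regions lost under siDRR were lost (2.88%), against 34 of 1859 at kept ones (1.83%), an odds ratio of 2.60 (0.712 to 6.60), which decides nothing. Lists of equal length gave 0.700, and the better-scoring 50% gave 0 because none of 67 was lost. Under siSmc3 the odds ratio was 4.54 (2.58 to 7.85), but 1.29 (0.479 to 2.69) at equal length and 1.72 (0.354 to 4.598) with the better-scoring 50%.

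ATAC gain at SMC3 sites differed with the settings. Under siDRR, 8.32% of 4473 ATAC regions with SMC3 were gained, against 5.996% of 35159 without, an odds ratio of 1.08 (0.943 to 1.22). It was 1.49 (1.29 to 1.70) at equal length, 1.398 (1.112 to 1.703) with the better-scoring 50%, and 0.893 (0.787 to 1.02) within strata of rank and width. Under siSmc3 the odds ratio was 0.652 (0.574 to 0.744), and 0.972 (0.774 to 1.20) with the better-scoring 50%. It stayed under 1 at equal length, at 0.777 (0.665 to 0.922), and within strata of rank and width, at 0.566 (0.492 to 0.645).

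Chromosomes took unlike shares of the lists. Chromosome 7 held 5.61% to 6.04% of SMC3 peaks, 4.23% to 4.86% of ATAC peaks, and 3.56% and 4.06% of the summits of ChIRP pool 2, against 5.18% and 4.93% of those of pool 1. Chromosome 8 held 8.29% of the summits in replicate 1 of pool 1 and 5.38% in replicate 2. Chromosome X differed more and the other way, at 1.59% and 6.85%, against 5.25% and 5.29% in pool 2.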
